A study of Homo sapiens with 12 samples.

How the data were processed

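Total messenger RNA profiles of MCF10A cells were measured on 12 Affymetrix arrays, 4 after transfection with a control siRNA and 4 after each of 2 mixes of siRNA against YAP and TAZ. Per the labels' protocols, cells were seeded on day 1, transfected with 33 nM siRNA on day 2, given fresh medium on day 3 and harvested on day 4. Groups and replicate letters A to D were taken from the sample titles, which call the arrays biological replicas. Nothing states that they came from separate cultures, so p-values measure the spread between these samples, part of which may be technical. The siRNA sequences, scan dates and raw scanner files were not used here.

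The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which give no version and no probe set definition. As commonly run, RMA subtracts background, makes the probe intensities of all arrays equal in distribution and summarises the probes of each probe set. Quantile normalization of this kind removes differences in total signal between arrays, so a change shared by most genes would not show, and summarised log2 values of dim probe sets understate fold changes. The table held 54675 probe sets with 0 missing values, between 2.36 and 15.15, and array medians lay between 6.11 and 6.14, so that depth was judged from signal: a probe set near the lower quartile of an array (4.57 to 4.62) has little room to show a fall. Through the platform annotation, 41097 probe sets had 1 gene symbol, 1801 several and 11777 none. Of these, 62 Affymetrix control probe sets were kept apart as quality measures. Gene identifiers of 41037 probe sets matched a current gene table and 0 symbols needed an update. From the 41091 probe sets used, the one with the highest mean over all 12 arrays represented each of 19775 genes. Probe sets of related genes, such as HLA, keratin, S100 and interferon-induced families, may share signal.

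A linear model with 3 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, no filter, prior degrees of freedom 3.42), with contrasts of each mix minus control and of mix 2 minus mix 1. P-values were adjusted by the Benjamini-Hochberg method over genes within a contrast, and a gene was called at an adjusted p under 0.05. All 3 contrasts of a gene share one standard error. Genes called with both mixes were compared with the overlap of independent lists of the same sizes and with the controls split into pairs. They were also compared with 20 simulations in which both mixes were unchanged and shared a simulated control group. There all 12 arrays were drawn, independently for each gene, around its control mean with its residual spread. Gene lists were tested with camera, two-sided, at a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over lists within a contrast.

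The test, the samples, 19 gene lists of 17 to 39 measured genes, the rule for named genes and 10 alternative settings, besides leaving out each array, were fixed before the data were examined. The lists cover YAP/TAZ-TEAD targets, Hippo components, DNA replication, mitosis, glycolysis, p53 targets, cholesterol, interferon-stimulated genes, squamous differentiation, luminal, basal and mesenchymal markers, actin and SRF targets, the integrated stress response, inflammatory cytokines, EGF and ERK feedback, Notch, TGF-beta and BMP, and lysosome and autophagy. The rule names YAP1, WWTR1, CCN1, CCN2 and ANKRD1 and, for both mixes, the 12 largest mean rises and the 12 largest mean falls called with both, with all 8 siRNA arrays beyond all 4 controls. It adds the 6 largest differences between the mixes each way without overlap and, for each list, up to 4 members called the same way with both mixes and up to 2 called between them. It gave 136 genes; genes named only by clone or reading frame were passed over.

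The alternatives were the mean of a gene's probe sets, its most variable probe set, no probe sets of the _x_at and _s_at kinds (prone to cross-hybridise), no genes below the median level of 7.16, the replicate letter as a block, an intensity trend with robust moderation, only the 8 arrays of each comparison, array weights, centring of each array on its median, and centring on reference genes (the 7 measured of 10 fixed, which were TBP, HPRT1, GUSB, PPIA, YWHAZ, SDHA and B2M), called reference-gene centring. Leaving out each array in turn kept each gene's probe set as chosen over 12 arrays. This form was chosen after seeing the data: a first run, which chose probe sets again from the arrays left, had turned the mix 2 value of THBS1. Both forms are given. Another 3 lists (MHC class II, hypoxia-responsive and NRF2 target genes), used only in the additional observations, were also chosen after values were seen.

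The procedure was tested on simulated data with the means and spread of these arrays and 200 changed genes among 19775. At a log2 change of 0.5 it recovered 76% of changed genes with mix 1, 84% with mix 2 and 86% between the mixes (38, 42 and 43 of 50). At a change of 1 or more it recovered 100%, with 10, 13 and 12 false calls. These simulations differed only in the group that was changed and in their random draws, so the rates do not rank the comparisons. A list shifted by 0.3 in the mix 1 contrast was recovered, and 0 unshifted lists were called by camera. Genes were simulated independently of each other, so false list calls among genes that vary together were not tested (estimated correlation 0.36 for mitosis genes). The share of changed genes was also far below the share called in these data, for which the recovery rates may differ. Probe sets with several or no gene symbols (13522) were left out of all gene counts and are counted once in the additional observations.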

Results

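Messenger RNA was measured in MCF10A cells, an established, non-transformed line of human mammary epithelium, after small interfering RNA (siRNA) against YAP and TAZ. YAP and TAZ, encoded by YAP1 and WWTR1, are transcriptional co-activators that act with TEAD transcription factors and are restrained by the Hippo kinase pathway. The 12 Affymetrix arrays fall into 3 groups of 4: a control siRNA and 2 different mixes of siRNA against both genes, here mix 1 and mix 2. Each group was transfected at 33 nM on day 2 and harvested on day 4. Values were available for 54675 probe sets on the log2 scale, between 2.36 and 15.15, with array medians of 6.11 to 6.14. One probe set was used for each of 19775 genes. Correlations across all 54675 probe sets, which are not independent replicates, were 0.995 to 0.998 between arrays of a group. They were 0.986 to 0.987 between control and mix 1 arrays and 0.981 to 0.984 between control and mix 2 arrays. Between mix 1 and mix 2 arrays they were 0.981 to 0.985. The number of arrays limits the precision of each value. Where a pair of values follows a gene in brackets, these are its log2 fold changes with mix 1 and with mix 2 against the control, with the standard error that both share (n = 4 arrays in each group). A single bracketed value is mix 2 minus mix 1.

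Array quality was examined through the control probe sets. The array of mix 2 replicate A stood apart in the hybridisation control bioB, at 10.1 against 6.57 to 7.0 on the other 11 arrays, and its added poly-A RNA controls lay above the highest other array by 0.48 (phe) to 0.67 (lys). With mix 1, 3 of these added controls lay below all control arrays: dap (at most 10.3 against at least 10.4), phe (7.54 to 7.88 against 7.92 to 8.18) and thr (7.70 to 7.99 against 8.09 to 8.42). The 3' probe set of ACTB exceeded the 5' probe set by 1.81 ± 0.11 (SD, n = 4) with control siRNA, 1.99 ± 0.071 with mix 1 and 2.16 ± 0.16 with mix 2. That difference between ends, a measure of RNA integrity, was 0.34 higher with mix 2 than with control on all 4 arrays (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 arrays allow; adjusted p = 0.114 over 4 tests). With mix 1 it was 0.18 higher (exact p = 0.0857), and for GAPDH the same measure was -0.05 with mix 1 (exact p = 0.0571) and 0.03 with mix 2 (exact p = 0.286).

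Both targeted genes fell with both mixes. YAP1 (gene identifier 10413) was at 12.20 ± 0.076 (log2, SD, n = 4) with control siRNA, 9.11 ± 0.019 with mix 1 and 8.77 ± 0.34 with mix 2, which left 11.7% and 9.29% of the control level. WWTR1 (gene identifier 25937) was at 11.11 ± 0.022, 8.0 ± 0.08 and 8.83 ± 0.08, which left 11.6% and 20.7%. The log2 fold changes of YAP1 were -3.09 ± 0.12 (SE; limma, Benjamini-Hochberg adjusted p = 4.7e-10) and -3.43 ± 0.12 (adjusted p = 1.1e-10); those of WWTR1 were -3.11 ± 0.051 (adjusted p = 3.5e-13) and -2.27 ± 0.051 (adjusted p = 2.9e-12). All 3 probe sets of each gene fell with both mixes, on 4 of 4 arrays. The other WWTR1 probe sets, dimmer with control siRNA (9.23 and 6.74), changed less: by -2.53 and -1.44 with mix 1, and by -1.815 and -0.91 with mix 2. Those of YAP1 changed by -3.37 and -3.06 with mix 1, and by -3.725 and -3.36 with mix 2. The percentages left therefore hold for the probe set used. WWTR1 was higher with mix 2 than with mix 1 by 0.83 ± 0.051 (adjusted p = 1.8e-08, 4 of 4 arrays). YAP1 was lower with mix 2 by -0.34 ± 0.12 (adjusted p = 0.0432), and its other probe sets differed by -0.29 (adjusted p = 2.9e-04 over probe sets) and -0.35 (0.0116). At nearly the same size (-0.35 to -0.33), the call of YAP1 ended with trend and robust moderation (adjusted p = 0.061), with only the 8 arrays compared (0.0836) and without any 1 control or mix 1 array or mix 2 replicate C (0.0509 to 0.0809).

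**Figure D1:**
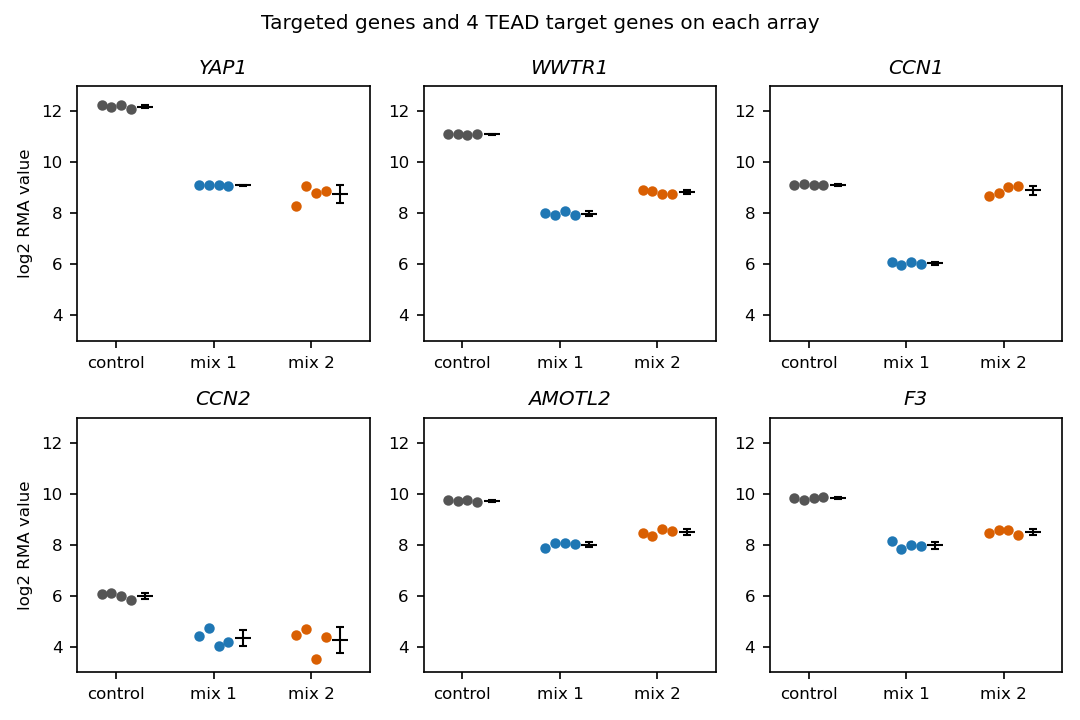
Log2 value of YAP1, WWTR1 and 4 genes known as targets of YAP/TAZ and TEAD (CCN1, CCN2, AMOTL2, F3) on each array of the 3 groups; points are arrays and bars are the mean ± SD of 4 arrays. YAP1 and WWTR1 lie below the control on all 8 siRNA arrays, while CCN1 lies at 6.05 with mix 1 and 8.90 with mix 2 against 9.12 with control.

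With mix 1, the gap junction connexin GJA1 rose by 5.97 ± 0.19 on the log2 scale (adjusted p = 6.5e-11) and the secreted chitinase-like protein CHI3L1 51.9-fold (5.70 ± 0.17). S100A7, a secreted calcium-binding protein of squamous epithelium, rose 28.1-fold, the lysosomal glycoprotein GPNMB 23.5-fold, and IGFBP3, which binds insulin-like growth factors, 19.7-fold. The MHC class II chain HLA-DPA1 rose by 4.50 ± 0.1. The control levels of GJA1 and HLA-DPA1 lay below the lower quartile of the arrays, against which the mix 1 levels were at least 41.4-fold and 17.9-fold higher. OLR1, a receptor for oxidised low-density lipoprotein, fell by 3.75 ± 0.14 on the log2 scale, the collagen chain COL8A1 fell by 3.60 ± 0.094 and follistatin (FST) fell by 3.46 ± 0.15. CCN1 and CCN2, matricellular proteins and textbook targets of YAP/TAZ with TEAD, changed by -3.07 ± 0.075 (adjusted p = 8.4e-12) and -1.66 ± 0.21 (adjusted p = 2.5e-05), on 4 of 4 arrays. CCN2 and OLR1 ended below that quartile, so that their falls are limited by it (at least 2.57-fold and 7.97-fold against it). ANKRD1, another such target, was dim in every group (4.08 with control, below the lower quartile of the arrays) and read -0.03 ± 0.092 (adjusted p = 0.854). In all, 8376 of 19775 genes (42.4%) passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, 3765 higher and 4611 lower, with a median absolute log2 change of 0.37. Of these, 446 were higher and 337 lower by at least 2-fold. For 8346 genes (42.2%) the 4 mix 1 arrays did not overlap the 4 control arrays, where chance gives 2.86%. With arrays centred on reference genes, which put the median change of all genes at 0.23 with mix 1, 0.09 with mix 2 and -0.14 between the mixes, 14132 genes passed and 85.0% of them were higher, against 45.0% here.

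With mix 2, the kinase gene DCLK1 rose by 5.59 ± 0.1 on the log2 scale (adjusted p = 8.2e-13) and the small GTPase gene RAB39B by 5.42 ± 0.25 (adjusted p = 1.1e-09). Their control levels lay below the lower quartile of the arrays, against which the mix 2 levels were at least 39.7-fold and 18.2-fold higher. The acetylcholine receptor subunit CHRNA9 rose 28.5-fold, AGR2, a protein folding factor of secretory epithelium, 18.9-fold, and chromogranin CHGB, a secretory granule protein, 13.9-fold. TNFRSF21, a receptor of the tumour necrosis factor family, fell by 4.21 ± 0.10 on the log2 scale (adjusted p = 4.5e-12), and OLR1 fell by 3.73 ± 0.14. The chemokine CXCL11 fell by 3.38 ± 0.12 and the protease inhibitor TFPI2 fell by 3.36 ± 0.15. CCN2 fell by 1.74 ± 0.21 (adjusted p = 1.3e-05, 4 of 4 arrays). OLR1, CXCL11, TFPI2 and CCN2 ended below the lower quartile, which limits these falls. CCN1 read -0.21 ± 0.075 (adjusted p = 0.0326). That call ended with only the 8 arrays compared (adjusted p = 0.0628), with array weights (0.0732), with reference-gene centring (0.208) and without any 1 of control replicates A to D or mix 2 replicates A and B (0.0542 to 0.0899). ANKRD1 read -0.06 ± 0.092 (adjusted p = 0.654). In all, 9292 genes (47.0%) passed the threshold, 4827 higher and 4465 lower, with a median absolute log2 change of 0.40. Of these, 590 were higher and 584 lower by at least 2-fold. Groups did not overlap for 8713 genes (44.1%), where chance gives 2.86%. Higher calls made up 51.9%, against 41.0% with arrays centred on their medians and 68.0% with reference-gene centring, and 9270 genes passed without mix 2 replicate A.

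The use of 2 mixes against the same genes allows changes shared by both to be set apart from those of a single mix. Both were set against the same control siRNA, with no other control group. An effect of that siRNA would therefore also appear as a shared change. By the largest mean rise, the shared genes were CHI3L1 (5.70 and 2.40 ± 0.17), RAB39B (2.38 and 5.42 ± 0.25), GJA1 (5.97 and 1.48 ± 0.19), AGR2 (2.46 and 4.24 ± 0.078), CHRNA9 (1.55 and 4.83 ± 0.084), PAPPA (2.75 and 3.62 ± 0.072), SNCAIP (3.77 and 2.37 ± 0.061), HLA-DPA1 (4.50 and 1.33 ± 0.1), PPP2R2C (3.14 and 2.65 ± 0.057), RHOU (3.50 and 2.23 ± 0.094), IQGAP2 (2.67 and 2.98 ± 0.075) and NCEH1 (3.06 and 2.55 ± 0.071). PAPPA is a secreted protease that cleaves binding proteins of insulin-like growth factors, and NCEH1 is a cholesteryl ester hydrolase. By the largest mean fall they were OLR1 (-3.75 and -3.73 ± 0.14), TFPI2 (-3.27 and -3.36 ± 0.15), YAP1, CXCL11 (-2.61 and -3.38 ± 0.12), FST (-3.46 and -2.51 ± 0.15), PTX3 (-2.86 and -2.61 ± 0.11), IL33 (-3.36 and -2.07 ± 0.17), WWTR1, COL8A1 (-3.60 and -1.51 ± 0.094), SLC44A2 (-2.25 and -2.75 ± 0.089), AOX1 (-3.01 and -1.83 ± 0.14) and IL13RA2 (-3.25 and -1.36 ± 0.12). FST binds and inhibits activins, PTX3 is a secreted pattern recognition protein and IL33 an epithelial cytokine. The control levels of RAB39B, GJA1 and HLA-DPA1, and the levels of OLR1, TFPI2 and CXCL11 with both mixes and of IL13RA2 with mix 1, lay below the lower quartile of the arrays. The sizes of these changes, and the order of these genes, are set in part by that limit. By the rule that picked these genes, all 8 siRNA arrays lay beyond all 4 control arrays for each of them. The highest adjusted p among them was 2.0e-05 (GJA1 with mix 2). Other probe sets of CHI3L1 (1 of 3, mix 2) and PAPPA (1 of 11, mix 1) were called the opposite way. HLA-DPA1 belongs to a family of similar sequences, between which probe sets may not separate fully.

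Over all genes, 6173 were called with both mixes, 4868 of them (78.9%) in the same direction: 2320 higher and 2548 lower, where independent lists of these sizes would share 919 and 1041. At least 2-fold with both mixes, 204 were higher and 127 lower. The other 1305 moved in opposite directions, 551 higher with mix 1 and 754 higher with mix 2, where independent lists would give 850 and 1125. Of the 4868, all 8 siRNA arrays lay beyond all 4 controls for 4376. Log2 fold changes of the mixes correlated across genes with a Pearson r of 0.503 and a Spearman rho of 0.481. Both comparisons used the same controls. In 20 simulations of unchanged groups with a shared control group, itself simulated, the mean r was 0.501 with no effect at all. There 0 genes were called the same way by limma (mean of 246.7 at an unadjusted p under 0.05, against 5503 observed). Genes were drawn independently of each other in these simulations. The covariance was 0.11 observed and 0.00344 simulated, a difference of 0.106. With the controls split so that each mix had its own pair, over 6 splits, 3916 to 3984 genes were called the same way and 946 to 1038 opposite, with an r of 0.476 to 0.490 and a covariance of 0.106 to 0.108.

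**Figure D2:**
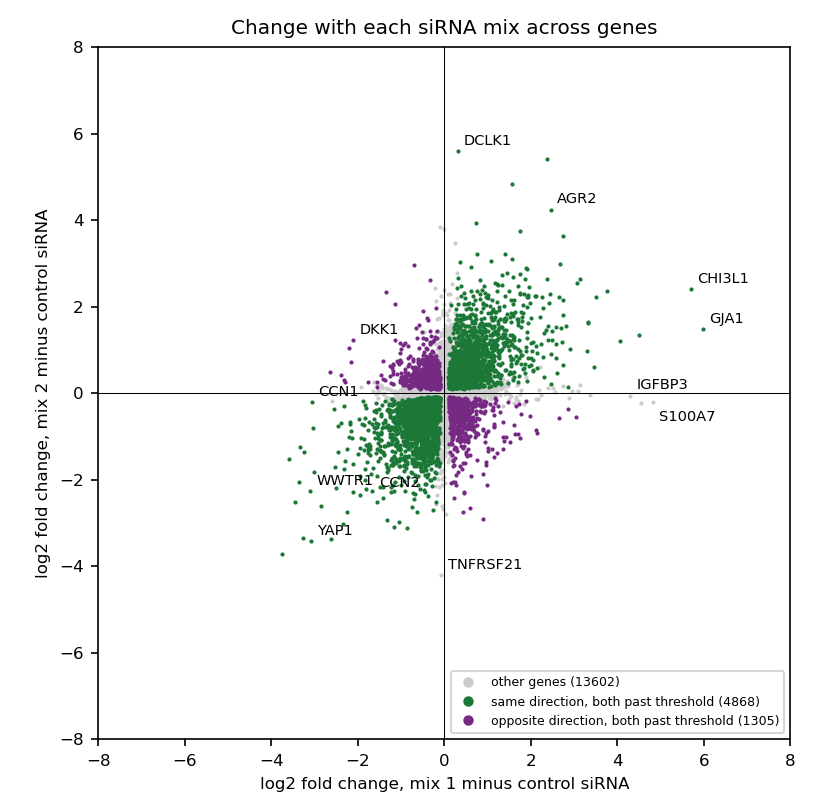
Log2 fold change of each of 19775 genes with mix 2 against that with mix 1, both relative to control siRNA; each point is a gene, green where both changes passed the threshold in the same direction (4868 genes) and purple where they passed in opposite directions (1305 genes). YAP1, WWTR1, CCN2, CHI3L1, GJA1 and AGR2 lie in the quadrants of the same direction, and CCN1, IGFBP3, S100A7, DCLK1 and TNFRSF21 lie near an axis.

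The mixes also differed from each other. DCLK1 was higher with mix 2 than with mix 1 by 5.29 ± 0.1 on the log2 scale, CHGB by 3.81 ± 0.073, the microtubule protein gene MAP2 by 3.69 ± 0.099, the protein kinase A inhibitor PKIB by 3.68 ± 0.17, the secreted Wnt antagonist DKK1 by 3.33 ± 0.073 and CHRNA9 by 3.28 ± 0.084. Lower with mix 2 were S100A7 (-5.03 ± 0.14), GPNMB (-4.79 ± 0.10), GJA1 (-4.49 ± 0.19), IGFBP3 (-4.36 ± 0.14), TNFRSF21 (-4.14 ± 0.10) and the glypican GPC6 (-3.81 ± 0.12). By the rule that picked these 12 genes, the 4 arrays of each mix did not overlap for any of them. Their highest adjusted p was 1.5e-09 (PKIB). MAP2 (-1.35 with mix 1 and 2.34 with mix 2), PKIB (-0.71 and 2.97), DKK1 (-2.11 and 1.23) and GPC6 (0.90 and -2.91) changed in opposite directions against the control, each past the threshold with both mixes. Against the control with mix 1, DCLK1 read 0.31 (adjusted p = 0.0234, 0.0535 to 0.0753 without control replicate A or D or mix 1 replicate B or C; near the lower quartile in both groups), CHGB -0.01 (0.952, but 0.24 and called under reference-gene centring) and TNFRSF21 -0.07 (0.655). With mix 2, S100A7 read -0.21 (0.248), GPNMB -0.23 (0.0853; below the lower quartile with mix 2, and called with arrays centred on their medians and without mix 2 replicate D) and IGFBP3 -0.06 (0.773). In all, 8712 genes (44.1%) differed between the mixes by limma with Benjamini-Hochberg adjustment, 5013 higher and 3699 lower with mix 2, and 473 and 564 by at least 2-fold. Groups did not overlap for 8062 genes (40.8%). Higher calls made up 57.5%, against 45.9% with arrays centred on their medians and 28.4% with reference-gene centring. Of the 4868 genes called the same way with both mixes, 2837 (58.3%) also differed between them.

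Gene lists were tested with camera, which compares the genes of a list with all other genes, at a preset correlation of 0.01 between genes. Of 19 lists, 5 passed an adjusted p of 0.05 with mix 1, 7 with mix 2 and 10 between the mixes. In each of these calls, the median of the list on all 4 arrays of one group lay beyond that on all 4 arrays of the other. This did not set called lists apart, since lists that were not called could separate as fully. With mix 1, for example, the Notch list lay at 0.064 to 0.131 against at most -0.0025 on the control arrays. With a correlation estimated from the data, the calls that held were the fall of YAP/TAZ-TEAD target genes with mix 1, their difference between the mixes, and the rise of cholesterol genes with mix 1. This setting differs from the preset in more than the correlation. For YAP/TAZ-TEAD targets with mix 1 the estimate was -0.0071, below the preset, yet the camera adjusted p rose from 2.2e-04 to 0.0323. P-values with an estimated correlation therefore do not measure only how the genes of a list vary together. The fry test asks whether the genes of a list move on balance one way, and its mixed form whether they change in either direction; neither compares a list with other genes. Fry passed for 19 lists with mix 1, 16 with mix 2 and 16 between the mixes, and its mixed form for 19 in each. No list call changed direction under any alternative.

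Of 21 measured YAP/TAZ-TEAD target genes (of 22 listed), 13 fell and 2 rose with mix 1 (median log2 change -0.42, adjusted p = 2.2e-04; 0.0323 with an estimated correlation). With mix 2, 9 fell and 8 rose (median -0.06, adjusted p = 0.687). Between the mixes, 14 were higher and 1 lower with mix 2 (median 0.48, adjusted p = 1.7e-04; 0.0295 with an estimated correlation). Counts adjusted over the list alone were the same in all 3 comparisons. With both mixes 9 fell and 1 rose, among them CCN2 (-1.66 and -1.74 ± 0.21), F3 (-1.85 and -1.32 ± 0.067), which starts blood coagulation, AMOTL2 (-1.71 and -1.23 ± 0.063), a junction protein that binds YAP, and CCN1, whose mix 2 call is limited as given above. IGFBP3 rose with mix 1, opposite to most of the list, and CCN1 and IGFBP3 differed most between the mixes (2.85 ± 0.075 and -4.36 ± 0.14). Of the 30 Hippo pathway and TEAD components, 8 rose and 8 fell with mix 1 (8 and 9 adjusted over the list alone), 8 rose and 10 fell with mix 2 and 9 were higher and 9 lower between the mixes (both the same over the list alone). The medians were 0.01, -0.08 and -0.02 (adjusted p = 0.717, 0.519 and 0.632). The mean with mix 1 was -0.18 and the test pointed down, and between the mixes the mean was 0.01 while the test pointed down. VGLL3 (-2.54 and -1.71 ± 0.15), a TEAD cofactor, and AJUBA (-1.18 and -1.45 ± 0.045), a LIM protein that inhibits LATS kinases, fell, as did the kinase adaptor MOB1A (-0.15 and -0.61 ± 0.041), though MOB1A read 0.10 with mix 1 under reference-gene centring. WWC1 (0.39 and 0.39 ± 0.051), an upstream activator of LATS kinases, rose, but read -0.49 with mix 2 on its most variable probe set and 0.16 with mix 1 (adjusted p = 0.213) without probe sets prone to cross-hybridise. The Hippo kinase gene STK3 fell by 1.0 ± 0.058 with mix 1 and read -0.09 ± 0.058 with mix 2 (adjusted p = 0.262). STK3 differed between the mixes by 0.92 ± 0.058, and VGLL3 by 0.83 ± 0.15.

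Mitosis genes moved in opposite directions with the mixes. Of 34, 25 rose and 1 fell with mix 1 (27 and 1 adjusted over the list alone; median 0.39, adjusted p = 1.7e-06; 0.382 with an estimated correlation). With mix 2, 33 fell and 1 rose (the same over the list alone; median -0.90, adjusted p = 2.5e-14; 0.120 with an estimated correlation), and 24 changed in opposite directions. Between the mixes 33 were lower with mix 2 and 0 higher by limma (the same over the list alone, and at an unadjusted p under 0.05; median -1.25, adjusted p = 5.7e-22; 0.104 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, read 0.70 ± 0.083 and -1.02 ± 0.083, and the spindle gene ASPM 0.45 ± 0.064 and -1.22 ± 0.064, both past the threshold with each mix. ASPM read -0.16 with mix 1 (adjusted p = 0.382) without probe sets prone to cross-hybridise and 0.19 (0.115) on the mean of its probe sets. The mitotic kinase AURKA (0.74 and 0.31 ± 0.044) rose with both, but its mix 2 value was 0.07 (adjusted p = 0.605) without those probe sets. The checkpoint kinase BUB1B (-0.17 and -1.24 ± 0.058) fell with both, but read 0.07 with mix 1 under reference-gene centring (adjusted p = 0.299) and was not called without control replicate A, B or C or mix 1 replicate A or D (adjusted p = 0.0544 to 0.0842). Of 39 measured DNA replication genes (of 40 listed), 19 fell and 5 rose with mix 1 (19 and 6 adjusted over the list alone; median -0.14, or 0.10 under reference-gene centring; adjusted p = 0.0797). It passed without mix 1 replicate B (adjusted p = 0.0302) or C (0.0482). With mix 2, 35 fell and 2 rose (the same over the list alone; median -0.87, adjusted p = 2.5e-14; 0.120 with an estimated correlation). Between the mixes 34 were lower with mix 2 and 0 higher by limma (the same over the list alone, with 0 higher at an unadjusted p under 0.05; median -0.63, adjusted p = 3.6e-15; 0.114 with an estimated correlation). The primase PRIM1 (-0.83 and -1.94 ± 0.082), the kinase CDC7 (-0.90 and -1.53 ± 0.072), the polymerase subunit POLE2 (-0.62 and -1.61 ± 0.068) and the licensing factor CDT1 (-0.58 and -1.63 ± 0.087) fell with both mixes. The ribonucleotide reductase subunit RRM2 rose with mix 1 (0.60 ± 0.061) and fell with mix 2 (-2.65 ± 0.061), and cyclin CCNE2 read -0.12 ± 0.07 (adjusted p = 0.213) and -2.18 ± 0.07 (adjusted p = 4.0e-11).

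**Figure D3:**
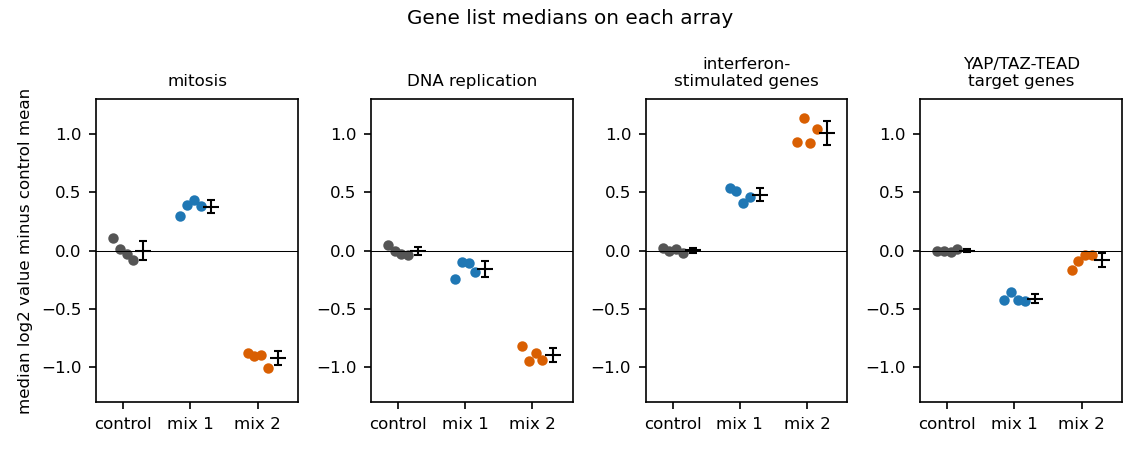
Median log2 value of the genes of 4 lists on each array, relative to the mean of the control arrays; points are arrays and bars are the mean ± SD of 4 arrays. Mitosis genes lie above the control with mix 1 and at or below -0.88 on each mix 2 array, and interferon-stimulated genes lie above the control on all 8 siRNA arrays.

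Interferon-stimulated genes rose with both mixes. Of 28 measured (of 30 listed), 18 rose and 4 fell with mix 1 (19 and 4 adjusted over the list alone; median 0.47, adjusted p = 9.8e-06; 0.220 with an estimated correlation). With mix 2, 25 rose and 1 fell (the same over the list alone; median 1.06, adjusted p = 7.2e-12; 0.106 with an estimated correlation). Between the mixes 17 were higher and 2 lower with mix 2 (19 and 3 adjusted over the list alone; median 0.51, adjusted p = 1.4e-04; 0.170 with an estimated correlation). Both mixes raised IFI27 (1.16 and 2.55 ± 0.11), IFI6 (1.78 and 1.53 ± 0.046), IFITM1 (1.05 and 2.01 ± 0.076) and the RNA-sensing synthetase OAS1 (1.73 and 1.23 ± 0.064), and 18 genes rose with both. IRF9, a subunit of the interferon-activated transcription factor, and IFIT1, which binds viral RNA, differed most between the mixes (1.46 ± 0.058 and 1.45 ± 0.088). Of 21 measured inflammatory cytokines and targets of NF-kB (of 25 listed), 11 rose and 5 fell with mix 1 (median 0.27, adjusted p = 0.104), a list that passed with the mean of each gene's probe sets (adjusted p = 0.0334). With mix 2, 14 fell and 2 rose (median -0.74, adjusted p = 1.5e-04; 0.137 with an estimated correlation), and counts adjusted over the list alone were the same for each mix. Between the mixes 13 were lower and 2 higher with mix 2 (14 and 2 adjusted over the list alone; median -0.94, adjusted p = 1.3e-06; 0.106 with an estimated correlation). The cytokines IL1B (-0.99 and -2.13 ± 0.068), IL1A (-0.38 and -1.88 ± 0.061) and IL24 (-0.59 and -0.74 ± 0.084) fell and LIF (0.28 and 1.15 ± 0.083) rose, though IL1A read 0.26 and 0.06 (not called) without probe sets prone to cross-hybridise, and -0.06 with mix 1 (adjusted p = 0.522) on the mean of its probe sets. LCN2, an iron-carrier protein of epithelial defence, rose with mix 1 (3.36 ± 0.098) and read -0.05 ± 0.098 with mix 2 (adjusted p = 0.735), and the chemokine CXCL3 rose with mix 1 (0.43 ± 0.096) and fell with mix 2 (-2.76 ± 0.096).

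Genes of cholesterol synthesis and uptake rose with mix 1. Of 19 measured (of 25 listed), 13 rose and 2 fell (15 and 3 adjusted over the list alone; median 0.40, adjusted p = 5.8e-05; 0.0475 with an estimated correlation). With mix 2, 9 rose and 4 fell (the same over the list alone; median 0.16, adjusted p = 0.180). Between the mixes 13 were lower and 4 higher with mix 2 (the same; median -0.26, adjusted p = 0.0046; 0.114 with an estimated correlation). The sterol sensor INSIG1 (1.91 and 1.41 ± 0.053) and the sterol enzymes TM7SF2 (0.66 and 1.29 ± 0.074), HMGCS1 (1.01 and 0.24 ± 0.051) and MSMO1 (0.77 and 0.33 ± 0.039) rose with both mixes. HMGCS1 read -0.13 with mix 2 on its most variable probe set (adjusted p = 0.247) and 0.06 on the mean (0.489). The cyclase LSS read 0.87 ± 0.046 (adjusted p = 5.8e-09) and -0.01 ± 0.046 (adjusted p = 0.826), and HMGCS1 differed between the mixes by -0.77 ± 0.051. Of 21 measured glycolysis genes (of 23 listed), 15 rose and 1 fell with mix 1 (the same adjusted over the list alone; median 0.28, adjusted p = 9.1e-05; 0.363 with an estimated correlation). With mix 2, 8 rose and 5 fell (the same; median 0.03, adjusted p = 0.687). Between the mixes 12 were lower and 4 higher with mix 2 (12 and 5 adjusted over the list alone; median -0.19, adjusted p = 0.0046; 0.397 with an estimated correlation). The glucose transporter SLC2A1 rose with mix 1 (2.56 ± 0.10, 5.91-fold) and read 0.03 ± 0.10 with mix 2 (adjusted p = 0.827), and PFKFB4 rose with mix 1 (1.07 ± 0.078) and read 0.17 ± 0.078 with mix 2 (adjusted p = 0.0888). That mix 2 value of PFKFB4 was called without dim genes (adjusted p = 0.0485), with trend and robust moderation (0.0483), with only the 8 arrays compared (0.0327), under reference-gene centring (0.26, adjusted p = 0.0113) and without mix 1 replicate B (0.0285). The aldolase ALDOC (0.78 and 0.88 ± 0.066) and the enolase ENO2 (0.35 and 0.76 ± 0.10) rose with both mixes, ENO2 from a control level below the lower quartile. The hexokinase HK2 (0.85 and 0.23 ± 0.044) and the transporter SLC2A3 (-1.38 and -0.68 ± 0.10) depended on the probe set: HK2 read -0.51 and -0.86, and SLC2A3 0.62 with mix 2, on their most variable probe sets.

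Targets of p53 rose with mix 2: of 21 measured (of 24 listed), 15 rose and 5 fell (the same adjusted over the list alone; median 0.46, adjusted p = 0.0017; 0.120 with an estimated correlation). With mix 1, 10 rose and 7 fell (10 and 8 adjusted over the list alone; median 0.10, adjusted p = 0.294). Between the mixes 11 were higher and 5 lower with mix 2 (the same; median 0.26, adjusted p = 0.0364; 0.246 with an estimated correlation), a call that ended without dim genes (adjusted p = 0.180) and without probe sets prone to cross-hybridise (0.129). The stress protein TP53INP1 (2.46 and 0.91 ± 0.043), the metabolic phosphatase TIGAR (0.64 and 1.51 ± 0.037) and the kinase PLK2 (0.29 and 1.41 ± 0.046) rose with both mixes and the DNA repair gene DDB2 (-0.73 and -0.43 ± 0.048) fell. TP53INP1 differed between the mixes by -1.55 ± 0.043 and the secreted factor GDF15 by 2.16 ± 0.066, or 0.02 (adjusted p = 0.891) without probe sets prone to cross-hybridise. GDF15 rose with mix 2 (1.97 ± 0.066), with a value of 0.20 (adjusted p = 0.101) without probe sets prone to cross-hybridise, and its mix 1 value of -0.19 ± 0.066 (adjusted p = 0.0342) was 0.18 without them and 0.05 under reference-gene centring. That mix 1 call of GDF15 also ended on the mean of its probe sets (-0.08, adjusted p = 0.313), with only the 8 arrays compared (adjusted p = 0.06) and without control replicate B or D or mix 1 replicate B, C or D (-0.18 to -0.14, adjusted p = 0.0724 to 0.107). Of 25 genes of the integrated stress response, 11 rose and 7 fell with mix 1 (the same adjusted over the list alone) and 12 rose and 8 fell with mix 2 (12 and 9). Between the mixes, 10 were higher and 11 lower with mix 2 (10 and 12). The medians were 0.06, 0.12 and -0.12 (adjusted p = 0.152, 0.687 and 0.516). The enzymes ALDH1L2 (-1.16 and -0.55 ± 0.098), SHMT2 (-0.67 and -0.42 ± 0.046) and CTH (-0.47 and -0.58 ± 0.073) fell and the transcription factor ATF3 (0.38 and 0.75 ± 0.058) rose with both mixes. ATF3 was not called with either (0.07 and 0.16) without probe sets prone to cross-hybridise. The lipoprotein receptor VLDLR rose by 1.70 ± 0.13 with mix 1 (adjusted p = 1.7e-07) from a control level below the lower quartile, where it also lay with mix 2 (0.20 ± 0.13, adjusted p = 0.241, or 0.0277 with only the 8 arrays compared). The serine synthesis enzyme PHGDH read 0.04 ± 0.06 (adjusted p = 0.702, but 0.28 and called under reference-gene centring) and 0.91 ± 0.06 (adjusted p = 3.2e-08).

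Basal and myoepithelial markers fell with mix 2. Of 17 measured (of 22 listed), 12 fell and 4 rose (the same adjusted over the list alone; median -0.50, adjusted p = 0.0026; 0.120 with an estimated correlation). With mix 1, 8 fell and 4 rose (9 and 4 adjusted over the list alone; median -0.14, adjusted p = 0.242). Between the mixes 11 were lower and 3 higher with mix 2 (11 and 4; median -0.44, adjusted p = 0.0039; 0.114 with an estimated correlation). The keratin KRT5 (-0.34 and -1.59 ± 0.04), the laminin chain LAMB3 (-0.25 and -1.60 ± 0.073), the caveolin CAV2 (-1.21 and -0.58 ± 0.069) and the linker protein DST (-0.57 and -1.01 ± 0.054) fell with both mixes. LAMB3 was not called with mix 1 under reference-gene centring (-0.01, adjusted p = 0.899). The oxytocin receptor OXTR read -0.40 ± 0.095 and 1.03 ± 0.095, and the keratin KRT15 0.92 ± 0.053 and -0.46 ± 0.053, each past the threshold with both mixes, except OXTR with mix 1 under reference-gene centring (-0.16, adjusted p = 0.146). DST was lower with mix 2 than with mix 1 by -0.44 ± 0.054 here but higher by 0.14 with the mean of its probe sets and by 0.55 on the most variable one. Of the 24 luminal epithelial markers, 10 rose and 3 fell with mix 2 (median 0.10, adjusted p = 0.0322; 0.304 with an estimated correlation), a call that ended without dim genes (adjusted p = 0.0908) and under reference-gene centring (0.0723). With mix 1, 7 rose and 5 fell (median 0.07, adjusted p = 0.152). Between the mixes 10 were higher and 4 lower (median 0.04, adjusted p = 0.345); adjusted over the list alone, all 3 comparisons gave the same counts. AGR2, the transcription factor ELF3 (1.69 and 1.64 ± 0.17) and the keratin KRT8 (0.58 and 1.22 ± 0.062) rose with both mixes, and the mucin MUC1 (-0.40 and -1.31 ± 0.063) fell, not called with mix 1 under reference-gene centring (-0.15, adjusted p = 0.0505). The secreted iron-binding protein LTF rose with mix 1 (3.12 ± 0.15) and read 0.19 ± 0.15 with mix 2 (adjusted p = 0.351). The transcription factor FOXA1 read -0.40 ± 0.066 and 1.73 ± 0.066, its mix 1 call ending on its most variable probe set (-0.12, adjusted p = 0.622) and under reference-gene centring (-0.16, adjusted p = 0.0575).

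**Figure D4:**
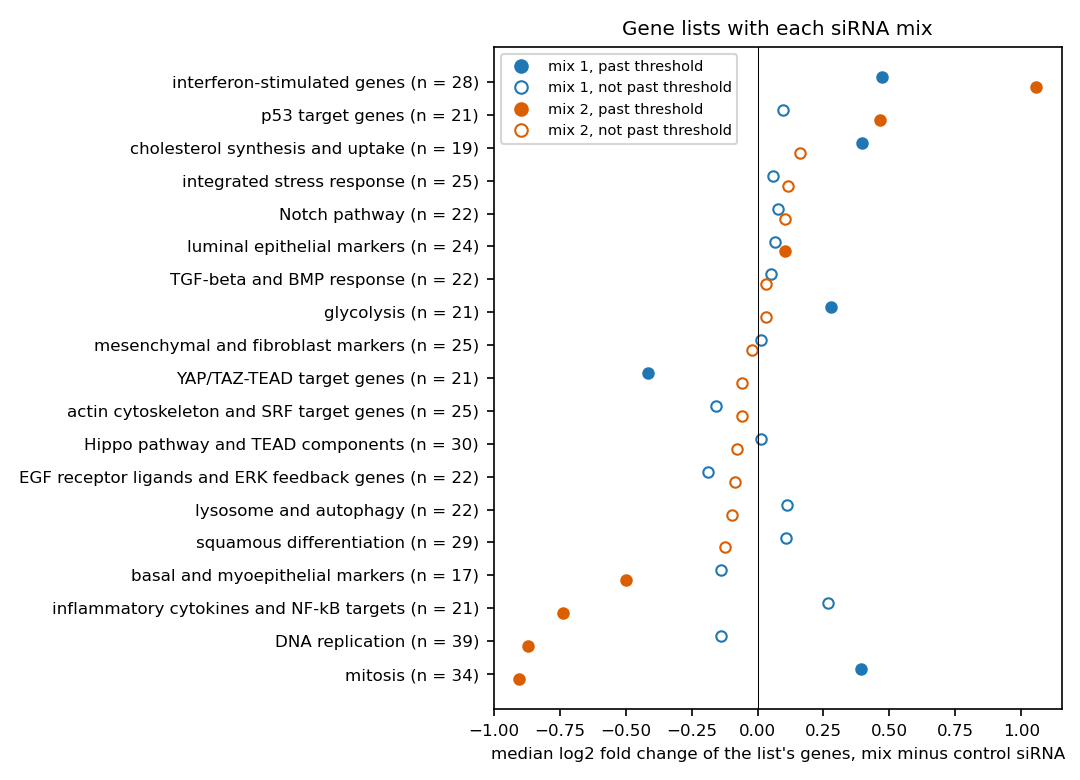
Median log2 fold change of the measured genes of each of the 19 lists with mix 1 and mix 2 against control siRNA; each point is 1 list and mix, filled where camera at the preset correlation passed the threshold. Mitosis lies at 0.39 with mix 1 and -0.90 with mix 2, and interferon-stimulated genes at 0.47 and 1.06.

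Of 29 measured genes of squamous differentiation (of 30 listed), 9 rose and 5 fell with mix 1 (median 0.11, adjusted p = 0.0729). It passed with the mean of each gene's probe sets (adjusted p = 0.0167), with the most variable probe set (0.0224) and without control replicate A (0.0146). With mix 2, 4 rose and 10 fell (median -0.12, adjusted p = 0.494). Between the mixes 11 were lower and 3 higher with mix 2 (median -0.10, adjusted p = 0.0077; 0.246 with an estimated correlation); counts adjusted over the list alone were the same. The transcription factor GRHL3 (1.29 and 0.96 ± 0.092) and the keratin KRT10 (0.91 and 0.35 ± 0.073) rose, and the cornified envelope genes SPRR1B (-0.23 and -0.84 ± 0.051) and IVL (-0.67 and -0.40 ± 0.079) fell, though SPRR1B read 0.01 with mix 1 under reference-gene centring. S100A7 and the protease inhibitor PI3 differed most between the mixes (-5.03 ± 0.14 and -1.93 ± 0.17), PI3 being higher than control with mix 1 (0.93 ± 0.17) and lower with mix 2 (-0.99 ± 0.17). Of 25 mesenchymal and fibroblast markers, 5 rose and 7 fell with mix 1 and 7 rose and 8 fell with mix 2. Between the mixes, 8 were higher and 6 lower with mix 2, and all of these counts were the same adjusted over the list alone. Their medians were 0.01, -0.02 and 0.01 (adjusted p = 0.702, 0.687 and 0.986), while the mean with mix 1 was -0.08 and the test pointed down with mix 1 and between the mixes, where the mean was 0.02. The matrix protease MMP2 (0.87 and 2.37 ± 0.086) rose, and the transcription factors SNAI2 (-0.61 and -1.92 ± 0.044) and ZEB1 (-0.93 and -0.93 ± 0.094) and the protease FAP (-1.59 and -0.44 ± 0.092) fell with both mixes. The fibrillin FBN1 read -0.59 ± 0.084 and 1.57 ± 0.084, and fibronectin FN1 0.95 ± 0.11 and -0.93 ± 0.11, but without probe sets prone to cross-hybridise FBN1 was not called with either mix (-0.09 and 0.22), and FN1 read 0.08 with mix 2. Of 25 measured genes of the actin cytoskeleton and SRF targets (of 28 listed), 4 rose and 11 fell with mix 1 and 4 rose and 6 fell with mix 2. Between the mixes, 13 were higher and 3 lower with mix 2, and all of these counts were the same adjusted over the list alone. The medians were -0.16, -0.06 and 0.14 (adjusted p = 0.152, 0.840 and 0.115). The mean with mix 2 was 0.07 while the test pointed down. The list passed with mix 1 on the mean of probe sets (adjusted p = 0.0138) and the most variable one (0.0224), and between the mixes without probe sets prone to cross-hybridise (0.0063). ACTA2 (0.15 and 2.03 ± 0.047), FERMT2 (0.93 and 1.12 ± 0.064) and TPM1 (0.83 and 0.63 ± 0.043) rose and ACTN1 (-0.73 and -0.15 ± 0.047) fell with both mixes. With mix 1 ACTA2 read 0.02 on the mean of its probe sets (adjusted p = 0.733) and was not called without control replicate A (0.14, adjusted p = 0.0604) or mix 1 replicate A (0.12, adjusted p = 0.0692), and with mix 2 ACTN1 read -0.06 under reference-gene centring (0.294). Between the mixes TPM1 read -0.20 ± 0.043 here but 1.08 on its most variable probe set, 0.24 without probe sets prone to cross-hybridise and 0.10 on the mean. ACTA2 and ACTN1 were higher with mix 2 than with mix 1 by 1.88 ± 0.047 and 0.57 ± 0.047.

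Of 22 measured EGF receptor ligands and ERK feedback genes (of 24 listed), 7 rose and 12 fell with mix 1 and 8 rose and 9 fell with mix 2. Between the mixes, 12 were higher and 6 lower with mix 2, and all of these counts were the same adjusted over the list alone. The medians were -0.19, -0.08 and 0.14 (adjusted p = 0.242, 0.905 and 0.345). With mix 2 the mean was 0.12 while the test pointed down. The ligand BTC (1.32 and 2.50 ± 0.086) and the feedback inhibitor SPRED1 (1.93 and 0.82 ± 0.08) rose, and the ligand TGFA (-1.62 and -0.42 ± 0.047) and the transcription factor EGR1 (-0.26 and -1.56 ± 0.038) fell. SPRED1 was not called with mix 2 on its most variable probe set (0.09, adjusted p = 0.334), nor EGR1 with mix 1 under reference-gene centring (-0.02, adjusted p = 0.651). The phosphatase DUSP4 fell with mix 1 (-0.42 ± 0.059) and rose with mix 2 (1.04 ± 0.059), and PHLDA1 read 0.03 ± 0.063 (adjusted p = 0.74) and 1.40 ± 0.063 (adjusted p = 7.7e-10). With mix 1, 3 of the 6 probe sets of PHLDA1 fell, and it read -0.25 on their mean (adjusted p = 4.9e-04) and 0.28 under reference-gene centring (0.0027). With mix 2, 1 of the 6 fell. Of the 22 Notch pathway genes, 9 rose and 5 fell with mix 1 and 9 rose and 3 fell with mix 2. Between the mixes, 7 were higher and 5 lower with mix 2, and all of these counts were the same adjusted over the list alone. The medians were 0.08, 0.11 and 0.03 (adjusted p = 0.104, 0.163 and 0.851). Without probe sets prone to cross-hybridise the list passed with mix 1 (adjusted p = 0.00663) and mix 2 (0.0163). The Notch effector HEY1 (1.23 and 2.52 ± 0.047), the ligand DLL1 (0.92 and 0.77 ± 0.075), the receptor NOTCH1 (0.58 and 0.39 ± 0.044) and the glycosyltransferase LFNG (0.44 and 0.52 ± 0.065) rose with both mixes. NOTCH1 was not called with mix 2 on the mean of its probe sets (0.13, adjusted p = 0.0504), and 1 of 2 probe sets of DLL1 fell with mix 2. HEY1 and the ligand DLL3 differed most between the mixes (1.30 ± 0.047 and 0.57 ± 0.079).

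Of 22 measured genes of the TGF-beta and BMP response (of 24 listed), 8 rose and 7 fell with mix 1 (the same adjusted over the list alone) and 6 rose and 7 fell with mix 2 (6 and 8). Between the mixes, 8 were higher and 9 lower with mix 2 (8 and 10). The medians were 0.05, 0.03 and 0.01 (adjusted p = 0.702, 0.901 and 0.632), while the test pointed down with mix 2 (mean 0.04) and between the mixes (mean -0.06). The inhibitors of differentiation ID2 (3.29 and 0.96 ± 0.23) and ID3 (1.56 and 1.12 ± 0.084) rose, and the activin subunit INHBA (-1.80 and -2.22 ± 0.085) and the receptor TGFBR1 (-1.18 and -2.12 ± 0.056) fell. TGFBR1 was not called with either mix (0.05 and -0.11) without probe sets prone to cross-hybridise. ID2 differed between the mixes by -2.33 ± 0.23 and thrombospondin THBS1 by 1.46 ± 0.12. THBS1 read 0.24 ± 0.12 with mix 1 (adjusted p = 0.137, but called at 0.48 under reference-gene centring and at 0.36 without mix 1 replicate A, and with 2 of 7 probe sets lower) and 1.70 ± 0.12 with mix 2 (adjusted p = 5.8e-08). It read 0.11 with mix 2 and -0.05 between the mixes without probe sets prone to cross-hybridise, and -0.12 to -0.06 with mix 2 when its probe set was chosen again without mix 2 replicate B, C or D. Of 22 measured genes of lysosome and autophagy (of 25 listed), 8 rose and 6 fell with mix 1 (10 and 6 adjusted over the list alone) and 8 rose and 8 fell with mix 2 (8 and 11). Between the mixes, 8 were higher and 10 lower with mix 2 (9 and 11). The medians were 0.11, -0.10 and -0.14 (adjusted p = 0.242, 0.687 and 0.160). Between the mixes the list passed on the mean of probe sets (adjusted p = 0.0201) and on the most variable one (0.0121). The lysosomal peptidase TPP1 (-1.02 and -1.27 ± 0.054) and the autophagy gene BECN1 (-0.30 and -1.27 ± 0.052) fell and WIPI1 (0.85 and 1.07 ± 0.058) and the autophagy receptor SQSTM1 (1.09 and 0.28 ± 0.042) rose with both mixes. Without probe sets prone to cross-hybridise, TPP1 was not called with either mix (-0.02 and -0.05) and BECN1 read -0.09 with mix 1 (adjusted p = 0.275; -0.06 and 0.328 under reference-gene centring), 0.09 with mix 2 and 0.18 between the mixes, and on its most variable probe set SQSTM1 read -0.16 with mix 2. The membrane protein LAMP2 and the proton pump subunit ATP6V1A were lower with mix 2 than with mix 1 by -1.15 ± 0.087 and -1.02 ± 0.041.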

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

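The tests of the explanations weighed here, and the counts over other splits of the arrays, were chosen only after the results were seen. For each group of 4 arrays, the array farthest out was compared with its nearest neighbour, relative to the range of the group (Dixon's criterion). An array stood apart in 38 of 495 groups (7.68%): 27 of 408 for named genes, 6 of 57 for list medians and 5 of 30 for control probe sets. Chance gives about 1 in 20 such groups. Mix 2 replicate A stood apart 11 times, and the next arrays 5 times.

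Mix 2 replicate A stood apart for the hybridisation control bioB (10.115), the poly-A controls dap (11.285), phe (8.6533) and thr (8.965), and the genes ACTN1 (12.52), BTC (7.50), CAV2 (11.92), IL1B (8.87), LAMB3 (10.70) and LAMP2 (10.36). Its median of cholesterol genes was 0.0825, against 0.1825 on the nearest array. Without this array, 8795 genes were called with mix 1, 9270 with mix 2, 5083 the same way with both, 1356 in opposite directions and 8611 between the mixes. Elsewhere with mix 2, replicate B stood apart for IVL (7.03), and replicate D for RRM2 (8.31) and the median of integrated stress response genes (0.1525). With mix 1, replicate A stood apart for ACTA2 (8.34), LAMB3 (11.97), POLE2 (8.13), SNAI2 (11.26) and the median of basal markers (-0.1175). Replicate B did so for CXCL11 (4.66), SQSTM1 (11.61), WWC1 (9.23), ZEB1 (6.63) and the median of YAP/TAZ-TEAD targets (-0.355), and replicate C for HK2 (11.56). With control siRNA, replicate A stood apart for AGR2 (6.50), PI3 (8.99), SLC2A1 (9.44) and the median of squamous genes (0.10). Replicate B did so for ALDH1L2 (9.84). Replicate C did so for LIF (6.25), LTF (5.34), PAPPA (5.99), the poly-A control phe (8.175) and the median of integrated stress response genes (-0.03), and replicate D for HK2 (10.65), MOB1A (11.17) and RHOU (6.19). All gene values are log2, and list medians are relative to the control mean.

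Effects of the mixes differed, by the test of mix 2 minus mix 1, for 10 lists. Median differences were 0.48 for YAP/TAZ-TEAD targets, -0.625 for DNA replication, -1.2537 for mitosis, -0.1925 for glycolysis, 0.26 for p53 targets and -0.255 for cholesterol genes. They were 0.505 for interferon-stimulated genes, -0.0975 for squamous differentiation, -0.4375 for basal markers and -0.94 for inflammatory genes. With an estimated correlation only the difference of YAP/TAZ-TEAD targets passed (adjusted p = 0.0295), and the other lists had an adjusted p of 0.104 to 0.397. Over all genes, 8712 differed between the mixes and 1305 changed in opposite directions. Among 13522 probe sets with no or several gene symbols, which no comparison used, 2214 were called with mix 1, 3132 with mix 2 and 1169 the same way with both, 104 of them at least 2-fold.

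The counts of called genes depended on the real grouping. Among the 35 splits of 8 arrays into groups of 4, only 1, the real one, gave as many genes. This held for mix 1 (8376), for mix 2 (9292) and between the mixes (8712). That share is the smallest that 35 splits allow, and the other splits mix groups that differ, which widens their spread. Chance differences between cultures are not covered, since nothing states that the arrays came from separate cultures. The highest other split gave 0 in each case by limma after Benjamini-Hochberg adjustment (2025, 2716 and 2739 at an unadjusted p under 0.05, against 9360, 10307 and 9718). For genes called the same way with both mixes, 1 of 100 splits of the 12 arrays gave as many (4868, the real one), and the highest other gave 0 (1119 at an unadjusted p under 0.05, against 5503).

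Mitosis genes rose with mix 1 and fell with mix 2. No single array decided this, since 12 of 12 fits without 1 array kept both list calls. The median difference was -1.27 beyond that of all genes (SD of the list median over control arrays 0.0815). This could hardly have come out otherwise, since the list was picked by a test against all other genes and normalization keeps array medians nearly equal. It is therefore no separate test of an equal shift of all genes between arrays. Shifts that depend on signal level were not tested. A weaker rise than with mix 1 was not what mix 2 gave, since the highest of the 4 mix 2 arrays lay at -0.879. That restates the pattern that was picked and is no separate test of a cause. With an estimated correlation, however, neither list call passed (adjusted p = 0.382 with mix 1 and 0.120 with mix 2), nor did their difference (0.104). An off-target effect of either mix, which may differ between siRNA sequences, was not tested and stays open.

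Interferon-stimulated genes rose with both mixes. The median rise of these genes with mix 1 exceeded that of all genes by 0.4825 (SD over control arrays 0.0203). That too follows from how the list was picked and from the normalization, so it is no separate test of an equal shift of all genes. Shifts that depend on signal level were not tested. With an estimated correlation the rises did not pass (adjusted p = 0.220 and 0.106). Sensing of double-stranded siRNA could raise such genes, and cannot be told apart here from an effect of losing YAP and TAZ: of 5 genes induced by RNA sensing (IFNB1, IFNL1, CCL5, CXCL10 and CXCL11), 0 were called higher with both mixes by limma (0 at an unadjusted p under 0.05). Of these, CXCL11 fell with both mixes, CXCL10 read 0.33 and -0.92, and the other 3 were dim in every group, with log2 changes of -0.09 and -0.03 (IFNB1), 0.13 and 0.14 (IFNL1) and 0.16 and 0.13 (CCL5) and adjusted p-values of 0.203 to 0.771.

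CCN1 fell far less with mix 2 than with mix 1. A misreading probe set is excluded, since the other CCN1 probe set differed between the mixes by 2.12 (adjusted p = 3.4e-08). Weaker depletion with mix 2 could act in this direction. On the probe sets used, more WWTR1 was left with mix 2 (20.7% against 11.6%) but less YAP1 (9.29% against 11.7%). Of 21 measured YAP/TAZ-TEAD targets, 14 were higher with mix 2 than with mix 1 and 1 was lower. Of the 13 targets that fell with mix 1, 10 were higher with mix 2 and 0 lower by limma (0 at an unadjusted p under 0.05). Choosing these by their fall on the same mix 1 arrays favours that direction. Weaker depletion cannot be told apart from off-target effects of either mix, which were not tested, since 3 of the 10 (MYOF, ASAP1 and DOCK5) rose above the control with mix 2 (0.50, 0.35 and 0.48), against what weaker depletion alone would give. CCN2 fell with mix 2 (-1.74) as with mix 1 (-1.66), but ended below the lower quartile of the arrays with both, where a further difference would not show.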

How the results depend on the processing

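Leaving out each array while keeping each gene's probe set was chosen only after the result was seen, in place of a first form that chose probe sets again; the other alternatives were planned. Over 10 settings and 12 fits without 1 array, 174 of 176 counts, 1237 of 1254 list values, 61 of 66 shares of higher calls, 8672 of 8820 gene values and 22 of 22 correlations held: tested values kept their direction and side of the threshold, counts stayed within 1.5 times, shares within 10 percentage points and correlations within 0.05. Without 1 array, counts ranged from 7760 to 8795 with mix 1, 8753 to 9334 with mix 2, 4494 to 5083 the same way with both, 1120 to 1356 in opposite directions and 8141 to 8640 between the mixes, with a correlation of 0.496 to 0.508. Under other settings they ranged from 6381 to 14132, 7278 to 10166, 3668 to 6722, 959 to 1483 and 6773 to 11035, with a correlation of 0.482 to 0.510. The count of 14132 with mix 1 came from reference-gene centring, which shifts all genes upwards. With the replicate letter as a block the counts were 8266, 9210, 4813, 1235 and 8671; of values given for named genes and lists, it changed only the calls of YAP1 between the mixes (-0.34, not called), GDF15 with mix 1 (-0.19, not called) and PFKFB4 with mix 2 (0.17, called). The letters did not pair the arrays: deviations of same-letter arrays correlated at -0.091 to 0.154, 2 of 12 pairs over 0.1, and 1 array correlated best with its own letter in both other groups. Lists past the threshold with mix 1 numbered 8 on the mean of probe sets, against 5, with squamous (0.14), actin (-0.22) and inflammatory genes (0.28) added. On the most variable probe set, squamous (0.14) and actin genes (-0.27) passed with mix 1 and lysosome genes between the mixes (-0.25; -0.14 on the mean). Without cross-hybridising probe sets, Notch genes passed with both mixes (0.12 each) and actin genes between them (0.23), and p53 targets between them did not (0.12). Luminal markers with mix 2 lost their call without dim genes (0.63) and under reference-gene centring (0.19), and p53 targets between the mixes without dim genes (0.26). Without 1 array, medians with mix 1 were -0.166 to -0.117 for DNA replication and 0.0558 to 0.118 for squamous genes. Gene values turned direction 27 times. Reference-gene centring adds 1 amount to all genes of a comparison, which by itself turned small negative values: MOB1A (0.095), BUB1B (0.07), GDF15 (0.0525) and SPRR1B (0.01), all with mix 1. For the others the cause was not tested. Without cross-hybridising probe sets, they were ASPM (-0.155), GDF15 (0.1825), IL1A (0.26) and TGFBR1 (0.0525) with mix 1, IL1A (0.0625), FN1 (0.08) and BECN1 (0.09) with mix 2, and BECN1 (0.1825), TPM1 (0.2375) and THBS1 (-0.0475) between the mixes. On the mean of probe sets, they were HK2 with both mixes (-0.0625 and -0.493), SLC2A3 with mix 2 (0.0383), and DST (0.141) and TPM1 (0.0988) between them. On the most variable probe set, they were HK2 (-0.51 and -0.858), WWC1 (-0.49), SLC2A3 (0.615), HMGCS1 (-0.128) and SQSTM1 (-0.16) with mix 2, with HK2 also with mix 1, and DST (0.5525) and TPM1 (1.08) between the mixes. In the first form, with probe sets chosen again, counts ranged from 7750 to 8789, 8748 to 9329, 4489 to 5080, 1123 to 1358 and 8130 to 8641. There 5674 values kept their side, 33 lost and 14 gained a call, and 3 turned: THBS1 with mix 2, at 1.70 on its usual probe set, ranged from -0.124 to 1.78, with -0.0642, -0.124 and -0.0608 without mix 2 replicates B, C and D, as another probe set was chosen. Of other gene values, 87 lost their call and 34 gained one. Signal limits these results for dim probe sets, near an array's lower quartile of 4.57 to 4.62.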

Other observations

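The 3 lists described here were chosen only after values were seen, as were the genes named in them. Their p-values, adjusted over these 3 lists only, do not account for that choice. MHC class II genes, which present peptides to T cells, rose with mix 1. Of 12, 9 rose and 0 fell by limma (9 and 1 adjusted over the list alone and at an unadjusted p under 0.05). Their median log2 change was 1.75 (camera adjusted p = 3.5e-07 over 3 lists, and adjusted p = 0.00797 with an estimated correlation), and 0.73 to 2.00 under the alternatives. The transactivator CIITA rose by 2.30 ± 0.094 (SE, n = 4; limma adjusted p = 5.1e-10), HLA-DRA by 2.94 ± 0.09, HLA-DMA by 3.46 ± 0.13 and the invariant chain CD74 by 2.46 ± 0.069. Under the alternatives CIITA ranged from 0.88 to 2.54 and CD74 from 0.80 to 2.71, all called. With mix 2, 5 rose and 0 fell by limma (the same over the list alone and at an unadjusted p under 0.05), with a median of 0.10 (adjusted p = 0.0844), and 0.04 to 0.20 under the alternatives. That list passed on the most variable probe set (0.20, adjusted p = 0.0278). CIITA read 0.38 with mix 2 (limma adjusted p = 0.00446; 0.17 to 0.47 under the alternatives) and HLA-DRA 0.05 (adjusted p = 0.68). HLA-DRA was called at 0.24 on the mean of its probe sets and at 0.43 on its most variable one. Between the mixes 8 were lower and 1 higher with mix 2 (the same over the list alone), with a median of -1.52 (adjusted p = 9.1e-06, and adjusted p = 0.0177 with an estimated correlation), and -1.67 to -0.73 under the alternatives.

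Hypoxia-responsive genes moved apart with the mixes. Of 18 measured (of 19 listed), 11 rose and 3 fell with mix 1, with a median of 0.19 (adjusted p = 0.00183, and adjusted p = 0.139 with an estimated correlation). With mix 2, 4 rose and 11 fell, with a median of -0.51 (adjusted p = 0.00126, and adjusted p = 0.174 with an estimated correlation). Between the mixes 15 were lower and 1 higher with mix 2, with a median of -0.70 (adjusted p = 4.5e-09, and adjusted p = 0.0177 with an estimated correlation). Adjusted over the list alone, these counts were the same. Under the alternatives the medians ranged from 0.17 to 0.43, from -0.60 to -0.32 and from -1.07 to -0.57. NDRG1 read 0.04 with mix 1 (limma adjusted p = 0.745), or 0.28 and called under reference-gene centring, and fell by 2.79 ± 0.079 with mix 2. The carbonic anhydrase CA12 rose by 0.76 ± 0.047 and fell by 0.74 with mix 2. BNIP3, a mitochondrial protein, rose by 1.42 ± 0.048 with mix 1 and 0.53 with mix 2, where its most variable probe set gave 0.15 (adjusted p = 0.109). Targets of NRF2, the regulator of antioxidant and detoxifying enzymes, rose with both mixes. Of 18 measured (of 19 listed), 13 rose and 0 fell with mix 1 by limma (14 and 0 adjusted over the list alone and at an unadjusted p under 0.05). Their median was 0.61 (adjusted p = 7.3e-09, and adjusted p = 0.00178 with an estimated correlation). With mix 2, 11 rose and 1 fell (the same over the list alone), with a median of 0.39 (adjusted p = 4.0e-05, and adjusted p = 0.0133 with an estimated correlation). Between the mixes 5 were higher and 7 lower with mix 2 (the same over the list alone), with a median of -0.03 (adjusted p = 0.0904). The reductase AKR1B10 rose by 2.81 ± 0.086 and 1.55, the glutathione peroxidase GPX2 by 1.56 ± 0.13 and 3.09, and malic enzyme ME1 by 1.10 ± 0.044 and 1.91. Under the alternatives GPX2 ranged from 0.89 to 1.80 and 1.71 to 3.23, and ME1 from 1.07 to 2.62 and 1.80 to 3.37, all called. AKR1C1, AKR1C2 and AKR1C3 are near-identical paralogs and count as 3 of the members.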
